A study of Mus musculus with 2 samples.

How the data were processed

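Expression was measured on 2 Affymetrix whole-transcript mouse arrays, 1 hybridised with pooled RNA of 3 ApoE-KO mice and 1 with pooled RNA of 3 UCP1/ApoE double-knockout (DKO) mice, all from inguinal white adipose tissue after a high-fat diet. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin as fragmented DNA. The authors deposited one linear intensity per probe set and array, which ranged from 3.55 to 23635.65. The scanner software, the background correction, the summarisation of probes and the scaling between arrays are not given in the sources used here. The unit was read from the values, which were all positive and right-skewed, and the column medians (152.1 and 157.65) differed, so the columns were not forced to 1 common median. The deposited intensities carry no detection call and no probe positions, so a low value was not separated from background and the part of a gene that a probe set reads is unknown here. Arrays were assigned to groups by their genotype labels. Pooling averages the mice before measurement, and nothing in the data measures the spread between mice or between arrays.

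Log2 of each intensity was taken with no pseudocount, and the value of the array labelled ApoE-KO was subtracted from that of the array labelled DKO. Probe sets were named through the platform annotation given with the data. Of 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and were left out, and 12147 were unnamed here. Entrez identifiers of 21698 of the named probe sets matched current RefSeq genes (GRCm38.p6), which changed 0 symbols, and the others kept the annotation's symbol. This table served only for names and for the order of genes on chromosomes. The named probe sets represented 19938 genes. For the 999 genes with several probe sets, the one with the highest mean over both arrays was used, and no gene named in the text had probe sets of opposite sign. The expression floor was the median of the mean log2 intensity over named probe sets, 7.62 (an intensity of 196.9), and 9891 genes lay on or above it. The floor is a rule of this work, not a detection limit.

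With 1 array per group there was no test, and genes were described by size. A gene above the floor was counted when its difference was at least 2-fold. Genes were named by a rule fixed before the data were examined. It took Ucp1 and Apoe, then the 12 genes with the largest positive and the 12 with the largest negative difference above the floor, leaving out predicted genes, RIKEN clones, receptor families, small RNAs and immunoglobulin segments, and then up to 4 members above the floor with the largest differences from each gene list. The 32 lists were fixed at the same time, covering thermogenic, white and general adipocyte genes, energy and lipid metabolism, stress responses, immune cells and other cell types that the depot or the dissection could hold. They had 724 entries, of which 645 distinct genes were measured and named here, and 15 of these were in more than 1 list. For each list, the median difference over all measured members was placed among the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins. A list was described as apart when it lay below percentile 2.5 or above percentile 97.5. Of the 32 lists, 10 lay above and 11 below, where 1.6 would be expected by chance if genes were independent, which genes of one pathway are not. These percentiles describe the 2 arrays and not the genotypes. A further 12 lists were written after the data had been seen. The neighbours of Ucp1 were the 20 nearest measured genes on each side, set against 10000 random windows of adjacent genes.

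The procedure was tested on simulated data built from the 9891 genes above the floor of this comparison. With 200 genes changed 4-fold, the size rule recovered 100.0% of them, and 0 unchanged genes were called under noise of the typical size seen. A 4-fold change passes a 2-fold rule by construction under such noise, so this checks the calculation and says nothing about how reliable a 2-fold difference between 2 single arrays is. A simulated list of 20 genes shifted by 0.5 lay at percentile 100.0, and 2.0% of 200 unshifted lists lay outside the central 95%. Genes were simulated as independent, so that share does not hold for lists whose members vary together. The alternatives fixed beforehand were quantile normalization, median centring, loess on mean intensity with a span of 0.4, an offset of 50 before the logarithm, the mean of a gene's probe sets, no floor or a floor at percentile 75, thresholds of 1.5-fold and 3-fold, lists restricted to members above the floor, the mean in place of the median, lists without shared genes, the calcium list without muscle members, and 10 neighbours of Ucp1 on each side. Some alternatives were added after seeing the data. They were intensities below the floor set to the floor and counts without the members of the muscle lists. The brown and beige list without some of the members that muscle also expresses, and the smooth muscle list without Des, were added then too. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.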

Results

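Gene expression was measured in inguinal white adipose tissue, the subcutaneous fat depot of the groin, of male C57BL/6J mice that lacked apolipoprotein E. One group lacked ApoE alone (ApoE-KO), and the other lacked both ApoE and uncoupling protein 1 (DKO). UCP1 is the inner mitochondrial membrane protein through which brown and beige adipocytes release energy as heat, and ApoE is a lipoprotein ligand whose loss makes mice hypercholesterolaemic. The mice lived at 23 °C and received a high-fat diet for 9 weeks from the age of 9 weeks. RNA from 3 mice of each genotype was pooled, and each pool was hybridised to 1 Affymetrix whole-transcript array, so the data consist of 2 arrays with 1 per genotype. The spread between mice was therefore not measured, no difference below has a replicate check, and no p-value is given. The 2 arrays had median intensities of 152.1 (labelled DKO) and 157.65 (labelled ApoE-KO) over 35557 probe sets. Differences are log2 values of the array labelled DKO minus the array labelled ApoE-KO, and precision is limited by the number of arrays. Among the 9891 genes above the expression floor, the middle 90% of differences lay between -0.52 and 0.76.

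The targeted genes were read first, as a check of the labels. The probe set for Ucp1 (10573152) had an intensity of 2229.9 in the array labelled DKO and 219 in the array labelled ApoE-KO, a difference of 3.35 or 10.2-fold. The Ucp1 signal was thus higher in the array whose mice were described as lacking UCP1, which goes against the label if the probe set reads the deleted part of the gene. Where the probes lie relative to the disrupted exons is not given in the sources used here, and a probe set outside the deletion checks nothing. For this reason the arrays are named by their labels throughout, and every direction below rests on those labels. The probe set for Apoe (10560624), the gene disrupted in both genotypes, had an intensity of 502 in the array labelled DKO and 589 in the array labelled ApoE-KO, a difference of -0.23. The 40 measured genes nearest to Ucp1, 20 on each side, had a median difference of 0.03, at percentile 84.1 of random windows of adjacent genes. Of these genes, 0 differed at least 2-fold, though Mmaa, named after its value was seen, came just short of it (0.997, or 1.995-fold).

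The main comparison asked how the fat of mice lacking both proteins differed in expression from that of mice lacking ApoE alone, under the series' heading of browning of this depot. At least 2-fold differences were found for 345 genes, of which 276 were higher and 69 lower in the array labelled DKO. Skeletal muscle lists held 27 of the 69. Of the 12 genes with the largest differences upward, 6 were in the brown and beige adipocyte list and 1 in the de novo lipogenesis list, 1 was Ucp1, and 4 were in no fixed list. An intensity below the floor of 196.9 was not told apart from background, and 4 of the 12 (Elovl3, Slc27a2, Dio2 and Dhrs9) lay there in the array labelled ApoE-KO. Elovl3, a cold-induced fatty acid elongase of brown fat, went from an intensity of 67.2 to 2009 (4.90, or 3.35 with the floor in place of the lower value). Slc27a2, a very-long-chain acyl-CoA synthetase, went from 161 to 2695 (4.06, or 3.78 with the floor). Fabp3, a fatty acid-binding protein of heart, muscle and brown fat, went from 334 to 4036 (3.59). Cox7a1, the muscle and brown fat isoform of a cytochrome c oxidase subunit, had a difference of 3.23, and Dio2, the deiodinase that activates thyroid hormone, one of 2.97 (2.26 with the floor). Cidea, a lipid droplet protein of brown adipocytes, followed with 2.90 and Elovl6, an elongase of saturated fatty acids, with 2.85. Adtrp, a hydrolase of fatty acid esters, differed by 2.80, Pank1, a pantothenate kinase of coenzyme A synthesis, by 2.71, the phosphatase Phospho1 by 2.69 and the dehydrogenase Dhrs9 by 2.55 (1.61 with the floor).

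**Figure D1:**
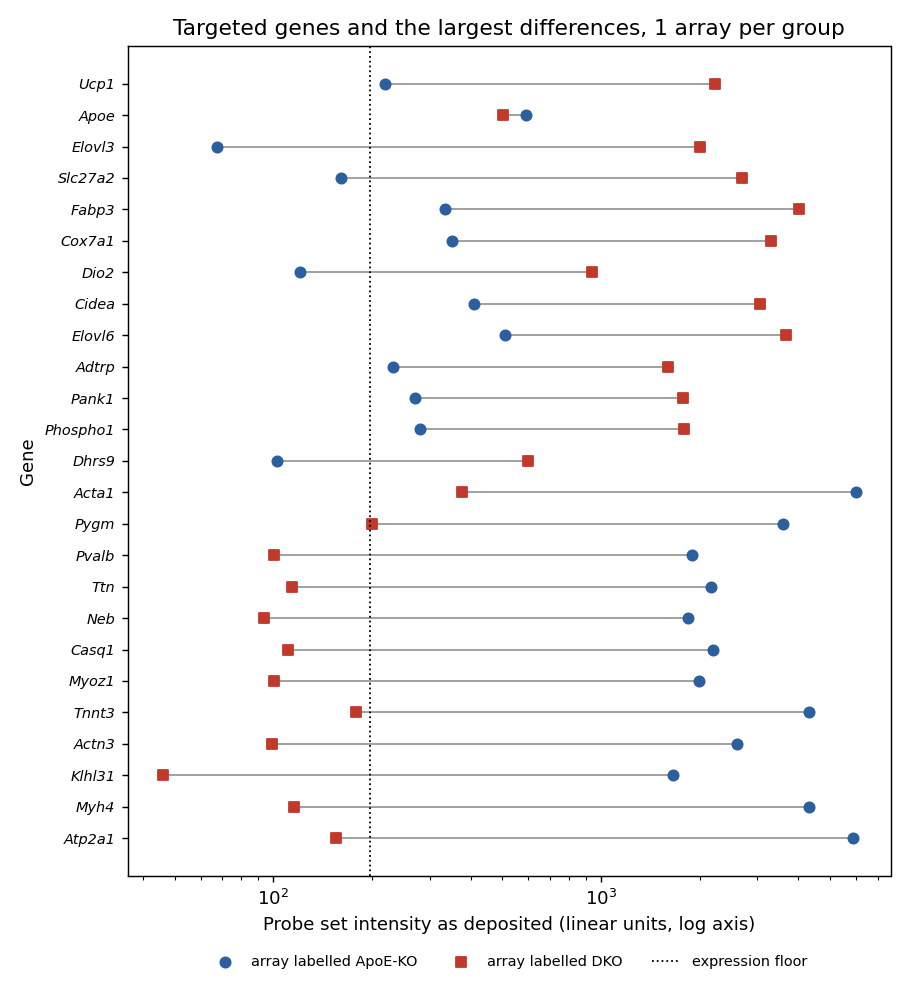
Probe set intensities on a log axis for Ucp1 and Apoe and for the genes with the largest differences each way, with 1 circle per gene for the array labelled ApoE-KO, 1 square for the array labelled DKO, and a dotted line at the expression floor of 196.9. Elovl3 stood at 2009 against 67.2, whereas Atp2a1 stood at 156 against 5899.5.

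Genes of brown and beige adipocytes were higher as a group. Of 29 measured members, with Ucp1 left out, 24 lay above the floor, 19 of these were at least 2-fold higher in the array labelled DKO and 0 at least 2-fold lower. The median difference of all 29 was 1.23, above all 10000 random lists matched on mean intensity. The members with the largest differences were Elovl3, Slc27a2, Fabp3 and Cox7a1. Not every marker took part: the transcription factor genes Prdm16 (0.13), Ebf2 (-0.21) and Tbx1 (-0.05), named after their values were seen, differed by less than 2-fold. Genes reported higher in white than in brown adipocytes had a median of -0.16 over 18 members, at percentile 2.21, with 0 members past 2-fold, and came inside the central 95% under quantile normalization (percentile 2.94) and loess (percentile 2.83). The largest among them were Nnat (-0.81), the corepressor gene Nrip1 (-0.64), and the Wnt antagonist Sfrp5 (-0.52). Markers shared by all mature adipocytes had a median of 0.06 over 16 members, at percentile 62.7. Gpd1, which makes glycerol 3-phosphate, was the single member past 2-fold, at 1.19, and Plin4, a lipid droplet coat protein, stood at -0.60.

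Genes of mitochondrial energy metabolism were higher as groups. All 23 measured genes of fatty acid oxidation were higher in the array labelled DKO and 17 of them at least 2-fold, with a median of 1.41. The thiolase gene Acaa2 (2.13), the very-long-chain acyl-CoA dehydrogenase gene Acadvl (2.13), the thioesterase gene Acot2 (2.02) and the carnitine-acylcarnitine carrier gene Slc25a20 (2.01) led this list, while Cpt1a, named after its value was seen, stood at 0.20. Of 50 nuclear genes of the respiratory chain and ATP synthase, 49 were higher and 33 at least 2-fold, with a median of 1.08. Cytochrome c (Cycs, 1.72), Sdhb of complex II (1.62), Uqcrfs1 of complex III (1.59) and Ndufv1 of complex I (1.58) had the largest differences. As the mean of its 3 probe sets, Cycs stood at 1.52, behind the other genes named. All 17 genes of the tricarboxylic acid cycle and pyruvate entry were higher, 13 at least 2-fold, with a median of 1.36, and the succinyl-CoA ligase genes Suclg1 (1.99) and Sucla2 (1.78) led them. Each of these 3 medians lay above all 10000 matched random lists.

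**Figure D2:**
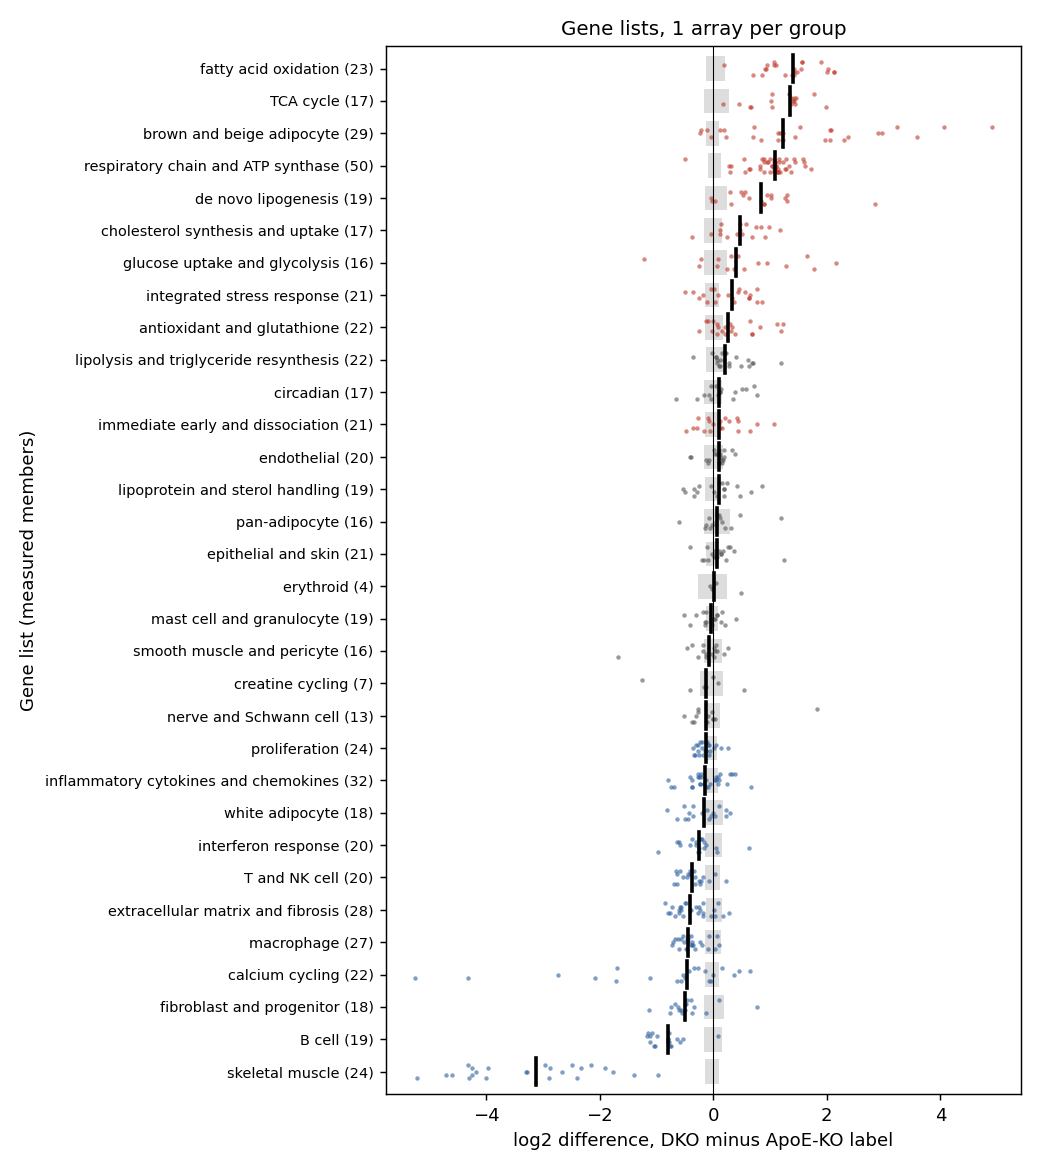
Differences (log2, DKO label minus ApoE-KO label) for the members of the 32 gene lists, 1 point per gene, with a black bar at each list's median and a grey band for the central 95% of matched random lists. Red and blue points mark lists above or below that band, from fatty acid oxidation at 1.41 to skeletal muscle at -3.11, and dark grey points mark lists inside it.

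Lipid synthesis genes were also higher, with smaller medians. De novo lipogenesis had a median of 0.85 over 19 members, above all 10000 random lists, with 6 at least 2-fold higher and 0 lower. Besides Elovl6, these included the acetyl-CoA carboxylase gene Acacb (1.30), the transketolase gene Tkt (1.30) and Acly, which makes cytosolic acetyl-CoA (1.27). Cholesterol synthesis and uptake had a median of 0.48 over 17 members, also above all random lists, and Nsdhl (1.18) was the 1 member past 2-fold. Glucose uptake and glycolysis had a median of 0.40 over 16 members, at percentile 99.8, with 4 members at least 2-fold higher. These were Pfkl (2.17), Pgam1 (1.78), Ldhb (1.65, or 1.53 as the mean of its 2 probe sets) and Pgk1 (1.29). Pfkm, the muscle isoform of phosphofructokinase, was the 1 member at least 2-fold lower (-1.21, named after its value was seen). Lipolysis and triglyceride resynthesis had a smaller median of 0.20 over 22 members, at percentile 97.1, inside the central 95% of random lists but outside it in 3 of 9 alternatives. Dgat1 (0.69), Agpat2 (0.69) and Gpam (0.62) of triglyceride synthesis were its largest members after Gpd1. Genes of lipoprotein and sterol handling had a median of 0.10 over 19 members, at percentile 92.1, with 0 members past 2-fold and Vldlr (0.85), Lipa (0.66), Lrp1 (-0.53) and Abcg1 (-0.50) as the largest.

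Heat-producing cycles described in mice without UCP1 were examined as separate lists. The creatine cycle had a median of -0.12 over 7 members, at percentile 17.2, and 0 of its 5 members above the floor reached 2-fold. This list holds a creatine kinase gene that muscle also expresses and was not run without it. Alpl stood at 0.54 (0.44 with the floor in place of its lower value), Gatm at -0.42, Slc6a8 at -0.16 and Ckb at -0.12. The calcium cycle had a median of -0.46 over 22 members, below all 10000 random lists, with 7 members at least 2-fold lower. Its largest members were Atp2a1 (-5.25, or -4.91 with the floor), Casq1 (-4.31, or -3.49), Ryr1 (-2.72, or -1.97) and Trdn (-2.09, or -3.06 as the mean of its 19 probe sets), which are skeletal muscle genes. Without its muscle members, the remaining 13 genes had a median of -0.14, at percentile 7.46. Atp2a2, the calcium pump of most other tissues, named after its value was seen, stood at 0.37.

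Stress and defence genes differed by small amounts. Targets of the integrated stress response had a median of 0.33 over 21 members, above all 10000 random lists, with 0 members past 2-fold. Vldlr (0.85), Trib3 (0.77), Cebpb (0.76) and Atf3 (0.64, or 0.46 with the floor) were the largest, and Fgf21, a hormone of this response named after its values were seen, lay below the floor in both arrays (intensities 148 and 114). Antioxidant and glutathione enzymes had a median of 0.26 over 22 members, at percentile 99.65, and the mitochondrial enzymes Sod2 (1.22) and Prdx3 (1.19) and the glutathione transferase Gsta4 (1.12) were at least 2-fold higher. Immediate early genes had a median of 0.11 over 21 members, at percentile 97.7, and Nr4a1 (1.07) was the 1 member past 2-fold. Among the 13 members above the floor, the median was -0.05, and this list came inside the central 95% in 4 of 9 alternatives. Clock genes, which follow the time of day, had a median of 0.11 over 17 members, at percentile 92.7, with Bhlhe40 at 0.78 and Nr1d1 at -0.65.

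Immune and stromal genes were lower as groups, mostly by less than 2-fold. B cell genes had a median of -0.80 over 19 members, below all 10000 random lists, and 7 members were at least 2-fold lower, led by Ms4a1 (-1.16), Fcer2a (-1.15), Cr2 (-1.11) and Cd79a (-1.10). This depot contains the inguinal lymph node. T and NK cell genes had a median of -0.37 over 20 members, with Cd2 at -0.69 and Cd3g at -0.65. Macrophage genes had a median of -0.44 over 27 members, with Cd163 at -0.72, Cybb at -0.71 and Clec10a at -0.67. Both medians lay below all 10000 random lists, with 0 members past 2-fold. Inflammatory cytokine and chemokine genes had a median of -0.15 over 32 members, at percentile 0.34, which came inside the central 95% with the mean of members (percentile 3.48) and with the floor as the lowest value (median 0). Only 13 of them lay above the floor, the largest being Cxcl13 (-0.80) and Cxcl10 (-0.69). Interferon response genes had a median of -0.25 over 20 members, at percentile 0.09, with Usp18 at -0.63 and Rsad2 at 0.64. Fibroblast and progenitor genes (median -0.49 over 18 members, Pi16 at -1.13) and extracellular matrix genes (median -0.40 over 28 members, Fn1 at -0.85, Col3a1 at -0.79) also lay below all random lists. Proliferation genes had a median of -0.13 over 24 members, at percentile 2.38, with 4 members above the floor, and came inside the central 95% in 5 of 9 alternatives. Endothelial genes (median 0.11 over 20 members), smooth muscle and pericyte genes (-0.08 over 16), nerve and Schwann cell genes (-0.12 over 13), mast cell and granulocyte genes (-0.03 over 19), epithelial and skin genes (0.06 over 21) and erythroid genes (0.02 over 4) lay inside the central 95% of random lists. The members above the floor that passed 2-fold in these lists were Des (-1.67), which skeletal muscle also expresses, and S100b (1.83, or 1.12 with the floor). Few members lay above the floor in the nerve (6), mast cell (4), epithelial (1) and erythroid (2) lists. These 4 lists therefore say little about whether those cells differed.

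Skeletal muscle genes had the largest median difference of the 32 lists. All 24 members were lower in the array labelled DKO, with a median of -3.11, and 19 of the 20 above the floor were at least 2-fold lower. The median intensity of the 24 genes was 115 in the array labelled DKO, below the floor of 196.9, and 1546 in the array labelled ApoE-KO. Of the 12 genes with the largest differences downward, 11 were in the muscle lists, the exception being Klhl31. They were the calcium pump gene Atp2a1 (-5.25), the fast myosin gene Myh4 (-5.22), Klhl31 (-5.17), Actn3 (-4.71), Tnnt3 (-4.60), Myoz1, Casq1, Neb, Ttn, Pvalb, Pygm and Acta1 (-3.99). Klhl31 has 2 probe sets, and their mean difference was -3.79. In 10 of these 12 genes the intensity in the array labelled DKO lay below the floor, and with the floor in its place their differences lay between -4.91 (Atp2a1) and -3.07 (Klhl31). The median of the 24 list members became -2.62 in the same way, still below all 10000 random lists. Every gene group given above, higher or lower, was thus measured beside muscle transcripts in the array labelled ApoE-KO. Of the 69 genes at least 2-fold lower, 27 belonged to this list, to the muscle members of the calcium cycle or to 2 muscle lists added after seeing the data, and 42 did not.

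**Figure D3:**
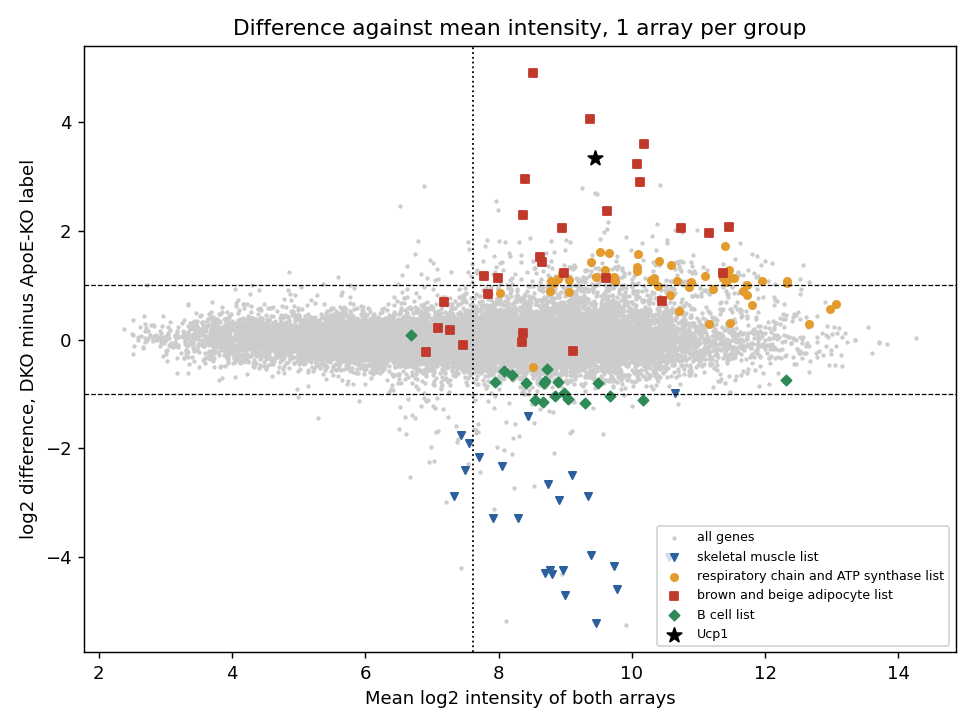
Difference between the arrays (log2, DKO label minus ApoE-KO label) against the mean log2 intensity of both arrays, 1 grey point per gene, with 4 gene lists and Ucp1 marked, dashed lines at 2-fold and a dotted line at the expression floor of 7.62. Respiratory chain genes lie near 1 at intensities across the upper range, and skeletal muscle genes reach -5.22.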

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

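The direction of Ucp1 (3.08 to 3.36) and Apoe (-0.25 to -0.21) held under the 5 alternatives run for them, and the neighbours of Ucp1 stayed inside the central 95% of windows. The count of genes at least 2-fold higher was 276 and stayed between 210 and 302 under other scalings and floors, whereas thresholds of 1.5-fold and 3-fold gave 749 and 52. The count of genes at least 2-fold lower was 69 and became 369 and 38 under those thresholds, 105 with no floor, 26 with the floor at percentile 75 and 42 without the members of the muscle lists, which do not hold every muscle gene (Klhl31 and Pfkm stay among the 42). With intensities below the floor set to the floor, 264 genes were at least 2-fold higher and 60 lower. In the 12 genes named with the largest differences each way, that setting brought Elovl3 from 4.90 to 3.35, behind Slc27a2 and Fabp3, and Klhl31 from -5.17 to -3.07, and the mean of its 2 probe sets put Klhl31 at -3.79. The share of 2-fold genes that were higher was 80%, and 67% and 57.8% at 1.5-fold and 3-fold. The threshold and floor settings move these counts by construction. Of 291 values of the fixed lists, 272 stayed on the same side of the percentile limits in the same direction. Part of this count was fixed by construction. Median centring shifts every gene alike and cannot move a percentile, and leaving out shared genes does not alter lists that have none. With only members above the floor, the immediate early list turned to -0.05 (percentile 32.83) and the proliferation list gave -0.11 (28.32), inside the limits. With the mean of members, the immediate early (0.14), inflammatory cytokine (-0.12) and proliferation (-0.14) lists came inside the limits and the epithelial and skin list (0.10, percentile 98.8) went outside. Without genes in more than 1 list, the immediate early list (0.11, percentile 96.84) came inside, and the lipolysis list (0.27) and the nerve list (-0.19) went outside. Under quantile normalization the proliferation (-0.08) and white adipocyte (-0.16, percentile 2.94) lists came inside and the lipolysis list (0.21, percentile 99.03) went outside. Under loess the white adipocyte list (-0.13) came inside and the lipolysis list (0.24) went outside. The mean of a gene's probe sets put the proliferation list (-0.13) at percentile 2.9, and leaving out muscle members put the calcium list (-0.14) at percentile 7.46. With intensities below the floor set to the floor, the medians of the immediate early, inflammatory cytokine, proliferation and second skeletal muscle lists became 0, inside the limits, since members below it in both arrays then differ by 0. Beyond these lost members and genes, the cause was not tested. Of 660 values of single named genes, 657 kept their side of 2-fold, the exceptions being Cr2 (-0.98) and Nr4a1 (0.99) with the offset and Pmvk (1.01) with loess. A gene with 1 probe set cannot change under the mean of probe sets, so part of this count was fixed too. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Low intensity limits the muscle, proliferation, cytokine, nerve, mast cell, epithelial and erythroid lists. Many of their members lay below the floor in 1 or both arrays.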

Other observations

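The tests on the Ucp1 signal, on the share of adipocytes and on the calcium cycle were chosen only after the results were seen. Their bounds were written after the values they used were known. The slow-fibre list, the values with the floor as the lowest value, and all lists and genes in the next paragraph were also chosen after the results. The tests on scaling, on brown fat of another depot and on a second muscle list had their predictions written before their values were looked at.

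Mitochondrial genes outside the fixed lists were also higher in the array labelled DKO. Of 77 genes of the mitochondrial ribosome, 76 were higher, with a median of 0.60 and 4 at least 2-fold. Coenzyme Q synthesis had a median of 1.04 over 12 members with 7 at least 2-fold, led by Coq6 (1.55, or 1.32 with the floor as the lowest value), and mitochondrial import and chaperone genes one of 0.67 over 26 members, with Timm9 at 1.44 (0.87 with the floor) and the chaperone gene Hspa9 at 1.18. Peroxisome genes had a median of 0.67 over 21 members, led by the fatty acyl transporter gene Abcd3 (1.84), and proteasome genes a median of 0.41 over 39. All 5 medians lay above all 10000 matched random lists, and breakdown of branched-chain amino acids (0.55 over 16 members, Bckdha at 1.05) at percentile 99.93. Cytosolic ribosome genes went the other way, with a median of -0.18 over 58 members, below all random lists, as did MHC class II genes (median -0.67 over 8 members, H2-Ob at -1.01). Genes of adrenergic and cAMP signalling had a median of -0.03 over 18 members, at percentile 37.66, although the adenylyl cyclase gene Adcy3 stood at 1.86. These differences rest on 1 array per label.

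The Ucp1 signal was 10.2-fold higher in the array described as lacking UCP1. One candidate explanation is that the 2 arrays carry each other's labels. In that case, and if the probes lie in the deleted part, the array labelled ApoE-KO should read only background. The bound for this was an intensity below the floor. An intensity over 2-fold above the floor was to argue against it. The Ucp1 intensity there was 1.11 times the floor. It thus lay between the 2 bounds, which were written after it was seen. Neither bound could decide, because a disrupted gene need not read as background here. Apoe, disrupted in both genotypes, read 502 in the array labelled DKO and 589 in the array labelled ApoE-KO, above the floor of 196.9. The other candidate explanation is that probes outside the deleted exons read a transcript of the disrupted locus in tissue with more thermogenic expression. The brown and beige list without Ucp1 was higher in the same array (median 1.23), as a label exchange would also give. The explanations cannot be told apart, because no value here locates the probes within the gene and both genotypes carry the same Apoe disruption. If the labels were exchanged, every direction in the results would turn.

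Thermogenic and mitochondrial genes were higher in the array labelled DKO. Intensity-dependent scaling between arrays is argued against, since the respiratory chain list lay above all 10000 lists matched on mean intensity. The bright cytosolic ribosome genes stood at -0.18. After loess the respiratory chain median was 1.10, still above matched lists. That percentile adds nothing further, because the random lists were already matched on the intensity that loess adjusts for. A larger share of adipocytes is argued against as the whole cause, since the pan-adipocyte median of 0.06 lay below the lower quartile of the respiratory chain members, 0.89. That bound was written after the results were seen. Brown fat of another depot in the pool stays open, because Zic1, a marker of classical brown fat, lay far below the floor in both arrays (difference -0.23) and Lhx8 just below it (-0.04), so neither could be read. The list of 6 classical brown fat markers was not higher either, with a median of -0.18 at percentile 5.24 and 5 members lower, but only 2 of its members reached the floor in the array labelled DKO, and with the floor as the lowest value its median was 0. The genotype itself, untested against the spread between mice, also stays open. Without some, but not all, of the members that muscle also expresses, the brown and beige list had a median of 0.99 over 20 members, above matched lists. Muscle transcripts were higher in the array labelled ApoE-KO, where the brown and beige list was lower, so this value does not bear on the cause.

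Skeletal muscle genes were lower in the array labelled DKO. Lower calcium-cycle expression in the fat itself was examined with the calcium list without its muscle members. That list had a median of -0.14 and a lower quartile of -0.43. The upper quartile of the skeletal muscle members was lower, at -2.38 (-1.34 with the floor as the lowest value). The remaining calcium genes were thus not lower by as much as muscle genes. The members that fell most were left out and the bounds were set afterwards, so this does not decide about the cause. Muscle tissue taken with the fat of the ApoE-KO pool may account for the lower muscle genes, and a second muscle list was used to test it. Of its 28 members 26 were lower, with a median of -0.76, below all 10000 matched random lists, though with the floor as the lowest value the median was 0. Of its 11 genes above the floor in the array labelled ApoE-KO, 7 (63.6%) were at least 2-fold lower, short of the 80% set beforehand for it and above the 50% under which it would have been argued against. Choosing genes by their level in that array alone favours lower values in the other, and by the floor on the mean of both arrays 1 of 5 members was at least 2-fold lower, a choice that in turn leaves out genes read in 1 array only, so this share does not decide. Slow-fibre genes had a median of -0.14 over 10 members, at percentile 5.32, with the genes Myh7 and Tnnt1 below the floor in both arrays. Muscle in 1 pool and a genotype effect on muscle genes cannot be told apart with 1 pool per genotype.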
